A study of Mus musculus with 2 samples.

How the data were processed

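RNA from mouse pancreatic islets was sequenced in 2 libraries, 1 from SRSF1 flox/flox mice and 1 from flox/flox mice with Ins2-Cre. The number of mice behind each library was not given in the sources used here. Per the labels, RNA was taken with Trizol, libraries followed a Lifetech protocol and sequencing used an Illumina NovaSeq instrument. Bowtie2 2.4.2 and the genome build mm10 are named in the submitters' processing notes. The read counter, the annotation release, filters and use of strand were not given in the sources used here.

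Read counts per gene were deposited as whole numbers without normalization, per the file headers. FPKM values were deposited beside these counts, per the file headers. In each library every FPKM equalled the count divided by the gene length and by 1 total, within a relative tolerance of 1e-06. The gene length in base pairs was deposited in the same table, per the file headers. The table used here held 21935 genes. Where rows shared a symbol, the row with the highest mean FPKM was kept, which left out 36 rows and kept 21899. Of these, 21861 gene identifiers were found in GENCODE M21, which uses the same genome build, and 21661 (98.9%) had identical start and end positions. Positions in the text are those of the deposited table.

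The planned description used FPKM, since the table was thought to hold no counts. FPKM remained the scale for log2 ratios and the counts were used for intervals, as planned for that case. The log2 ratio was log2((FPKM of the library labelled knockout + 1)/(FPKM of the control + 1)). Genes with a mean of at least 1 FPKM over both libraries and a log2 ratio of at least 1 or at most -1 were counted. With 1 library per group no p-value, standard error or count model was used. A ratio of counts, scaled by the library totals, has a 95% exact binomial interval (Clopper-Pearson, conditional on the sum of both counts). This interval covers counting error of reads only. Reads without molecular identifiers are not independent molecules, so the interval can be too narrow even for that error. Folds given in the text are these ratios of counts unless log2 is named. A gene at 0 reads in the library labelled knockout has a fold against a floor of 3 reads per library, or 0.189 reads per 1000000 in the control and 0.162 in the other library. This floor is a fixed convention and lies closer than the end of the 95% interval would, so these folds are not interval bounds.

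Gene lists (37) were written before the data were examined. Each list's median log2 ratio, over members with a mean of at least 1 FPKM, was placed among 10000 random lists of the same size, drawn with replacement from genes in the same of 20 bins of mean FPKM. The percentile describes these 2 libraries and is not a test between genotypes. Members at least 1.5-fold higher or lower on the log2(FPKM + 1) scale were counted. Lists with fewer than 3 measured members have values only. Named genes followed a rule fixed at the same time: Srsf1, 5 islet hormone genes, the 10 highest and 10 lowest named genes with a mean of at least 5 FPKM, up to 4 members of each list outside the central 95% of random lists and at most 2 members of each other list. Genes named outside the rule are marked as chosen after their values were seen, apart from genes that overlap a named gene. One gene that the rule takes is not reported here. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.

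The procedure was tested on simulated counts for the same 21899 genes, with counting error only. For the comparison of knockout with control, the 2-fold rule recovered 49 of 50 genes simulated 4-fold higher and 50 of 50 simulated 4-fold lower, but 32 of 50 in each direction at 2.5-fold, and it took 2 of 9890 unchanged genes. Intervals held the true ratio for 95.3% of unchanged genes. Of 100 unchanged lists, 3 fell outside the central 95% of random lists, and 100 of 100 lists raised by 0.5 on the log2 scale did. The members of these simulated lists were drawn at random, so the rates do not carry over to lists of genes expressed together. Alternatives were other pseudocounts, filters, thresholds, scalings, summaries of a list, treatment of shared members and treatment of repeated symbols. One more, which removes the trend of the log2 ratio with gene length by a lowess fit over a share of 0.3 of the genes, was chosen after seeing the data.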

Results

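Gene expression was measured by RNA sequencing in pancreatic islets, the clusters of endocrine cells that secrete insulin, glucagon and other hormones, from mice of 2 genotypes. In the control library both copies of Srsf1, which encodes a serine/arginine-rich splicing factor, carried loxP sites (flox/flox). The other library came from flox/flox mice that also carried Cre recombinase under the insulin 2 promoter, which is active in beta cells, and it is called the library labelled knockout. There was 1 library per genotype, so no difference has a replicate check and no test between the genotypes could be made. The control library held 15836364 counted reads and the library labelled knockout 18471375. Intervals in parentheses are 95% exact (Clopper-Pearson) intervals of a ratio of read counts. They cover counting error of reads only and say nothing of differences between mice or islet preparations. They can be too narrow even for that error, because reads are not independent molecules.

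Srsf1 itself was not lower in the library labelled knockout. It had 516 reads in the control and 592 in the other library, or 5.71 and 5.61 FPKM, a ratio of 0.984 (0.873 to 1.11). The gene lies on chromosome 11, from 88047373 to 88053755 on the plus strand (mm10), and overlaps the antisense gene Gm11508. Coding sequence makes up 14.7% of the merged exon length of its protein-coding transcripts, and the rest is untranslated. The value pools all exons of the gene, and the exons placed between loxP sites were not stated in the sources used here. Because the target does not separate the libraries, every direction given here is between 2 libraries by their labels.

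Most genes were at similar levels in the 2 libraries. Among 10079 genes with a mean of at least 1 FPKM, 90.5% differed by less than 1.5-fold on the log2(FPKM + 1) scale. Pearson's r on that scale across 21899 genes was 0.985 (Spearman's rho 0.959, genes not being independent replicates). In the library labelled knockout 55 genes were at least 2-fold higher and 226 at least 2-fold lower, on the log2(FPKM + 1) scale, which understates differences of genes of low expression. The counting interval excluded 1 for 53 and 224 of them, which adds little, because they were selected by size in the same 2 libraries. With totals set equal after leaving out the 20 genes of highest expression, the numbers were 85 and 165, so that the higher genes made up 34.0% in place of 19.6%. This scaling moved the median log2 ratio of all genes by 0.15, from -0.02 to 0.13.

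**Figure D1:**
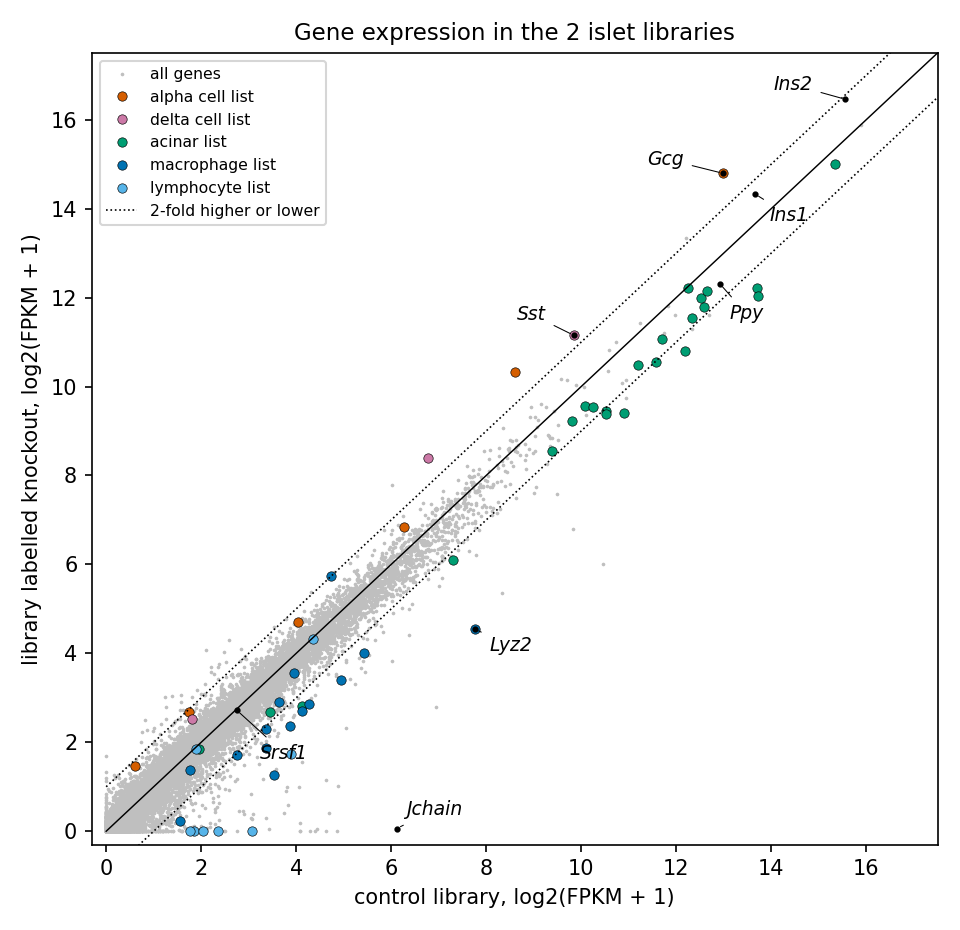
Each grey point is a gene, with log2(FPKM + 1) in the control library on the x axis and in the library labelled knockout on the y axis; coloured points are members of 5 gene lists with a mean of at least 1 FPKM, the solid line marks equal values and the dotted lines a 2-fold difference. Gcg and Sst lie above the dotted lines, Srsf1 lies on the line of equal values, and acinar, macrophage and lymphocyte genes lie mostly below it.

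Hormone genes of alpha, delta and beta cells took a larger part of the library labelled knockout. Gcg, which encodes glucagon (chromosome 2, 62474530 to 62483650), had 192778 reads in the control and 783052 in the other library, 3.48-fold higher (3.47 to 3.50). Sst, the somatostatin gene of delta cells (chromosome 16, 23889573 to 23890958), was 2.46-fold higher (2.41 to 2.52). Ins2 (chromosome 7, 142678656 to 142743381) was 1.88-fold higher and Ins1 (chromosome 19, 52264297 to 52265476) 1.59-fold higher, and together they took 7.69% of the control reads and 14.0% of the others. Reads of these near-identical insulin genes can be split between them by the counting. Iapp, the gene of amylin, which beta cells secrete with insulin (named after its values were seen), took 5.94% and 5.83%. Ppy, which encodes pancreatic polypeptide (chromosome 11, 102099930 to 102101319), went the other way, with 61150 and 47030 reads, a ratio of 0.659 (0.651 to 0.667), while Pyy, the peptide YY gene, was 2.22-fold higher (2.19 to 2.24).

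All 3 measured members of the delta cell list and 5 of the 6 measured members of the alpha cell list were at least 1.5-fold higher. The median log2 ratio was 1.30 for the delta list (percentile 99.985 among 10000 random lists of matched expression) and 0.89 for the alpha list (percentile 100). With no filter, over all members in the table, the delta median was 0.72 and the alpha median 0.66, and the alpha median was 1.36 with a pseudocount of 0.1 FPKM and 0.55 with one of 5 FPKM. In the alpha list, Ttr, which encodes transthyretin, was 3.31-fold higher (3.23 to 3.40), and Irx2, a transcription factor of alpha cells, was 3.37-fold higher (2.19 to 5.34). In the delta list, Rbp4 (retinol-binding protein) was 3.05-fold higher (2.91 to 3.20) and the transcription factor Hhex 1.90-fold higher (1.60 to 2.25). In the same libraries the acinar list was lower (median -0.80) and the endothelial list was at -0.16.

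Lists of beta-cell function were slightly higher, with few members past 1.5-fold. Granule and exocytosis genes are shared with alpha and delta cells, whose lists were higher too (medians 0.89 and 1.30), while 10 beta-restricted genes, listed after the values were seen, had a median of 0.03, with 6 higher and 4 lower. The median was 0.28 for exocytosis machinery (percentile 99.96; 0 of 14 members at least 1.5-fold higher), 0.23 for secretory granule and prohormone processing (percentile 99.98; 5 of 19 higher and 1 lower), 0.21 for glucose sensing and excitability (percentile 99.75; 0 of 15) and 0.15 for beta-cell transcription factors (percentile 98.4; 1 of 16). Among their members, Pcsk2, a prohormone convertase, was 1.56-fold higher (1.53 to 1.60), Abcc8, a subunit of the ATP-sensitive potassium channel, 1.45-fold (1.40 to 1.51), Syt13, which encodes a synaptotagmin, 1.34-fold (1.29 to 1.40) and Foxa2 1.57-fold (1.36 to 1.83). Of the 10 beta-restricted genes, the transcription factors Pdx1 and Nkx6-1 each had a ratio of 1.02 (0.907 to 1.15 and 0.948 to 1.09). The transcription factor Mafa (59 and 42 reads) had a ratio of 0.610 (0.401 to 0.922). G6pc2, in the glucose sensing list, had one of 0.782 (0.761 to 0.804). Each was named after its values were seen. Summed FPKM of the glucose sensing list was 774 in the control and 751 in the other library. Genes normally kept low in mature beta cells had a median of -0.43 (percentile 0.02), with 5 of 13 at least 1.5-fold lower and 0 higher. Several of them are also expressed by immune and stromal cells, whose lists were lower in the same library (medians -1.40 for macrophages, -1.95 for lymphocytes and -1.34 for mesenchymal cells). They included Ldha, which encodes lactate dehydrogenase A, with a ratio of 0.417 (0.383 to 0.454), and Mgst1, a microsomal glutathione transferase, 3.93-fold lower (3.52 to 4.41). The transcription factor list came back inside the central 95% of random lists with a pseudocount of 0.1, with no filter and with a mean of at least 5 FPKM, and the glucose sensing list did so with a mean over members. With totals set equal without the 20 highest genes, the first 4 medians were 0.45, 0.41, 0.38 and 0.32. On that scaling the median of the 10 beta-restricted genes was 0.20, with 8 higher and 2 lower. Their median was 0.10 with median centring, 0.03 with equal totals over all genes and 0.16 with the gene length trend removed. The glucose sensing median was 0.14 with a pseudocount of 5 FPKM. The transcription factor median was 0.22 with median centring. The median of genes kept low in mature beta cells was -0.19 with a pseudocount of 5 FPKM, -0.72 with equal totals over all genes and -0.70 with a mean of at least 5 FPKM.

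Digestive enzyme genes of acinar cells, the exocrine cells that surround islets, were lower. Of 23 measured members of the acinar list, 17 were at least 1.5-fold lower and 0 were higher, with a median log2 ratio of -0.80 (percentile 0). The list took 14.9% of the control reads and 9.29% of the others. Reg1 was 3.22-fold lower (3.19 to 3.25), Try5, a trypsinogen gene, 2.78-fold (2.76 to 2.81), Zg16, a zymogen granule protein, 2.81-fold (2.76 to 2.87) and Clps, which encodes colipase, 2.64-fold (2.59 to 2.68). Reg and trypsinogen genes belong to families of close copies, so the split of reads within each family is uncertain. Ductal genes had a median of -0.32, inside the random range (percentile 6.43), although Spp1 (osteopontin) was 2.13-fold lower (2.05 to 2.21) and Krt19 (keratin 19) 1.46-fold lower (1.39 to 1.54).

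Immune, stromal and red-cell genes were lower. With the filter of at least 1 FPKM, the medians were -2.82 for haemoglobin and red-cell genes (percentile 0.02; 3 of 3 members at least 1.5-fold lower), -1.95 for lymphocytes (percentile 0; 6 of 8), -1.40 for macrophages (percentile 0; 12 of 15) and -1.34 for mesenchymal cells (percentile 0.02; 5 of 5, out of 15 listed). With no filter the medians were -1.80, -1.49, -1.05 and -0.46 in the same order, and with a pseudocount of 5 FPKM -1.59, -0.65, -0.90 and -0.49. With a pseudocount of 0.1 FPKM the lymphocyte and mesenchymal medians were -4.70 and -2.64. Their size and their order against other lists thus depend on both choices. In the lymphocyte list 5 members had 0 reads in the library labelled knockout, and the median was -4.76 with such members at the floor of 3 reads per library. Cd79b, a B-cell receptor subunit, had 168 reads in the control and 0 in the other library, 65.3-fold lower against that floor. The T-cell adhesion gene Cd2 (86 and 0 reads) was 33.4-fold lower against it. The 95% intervals allow smaller folds, down to 52.5 and 26.6. Lyz2, the lysozyme gene of macrophages and other myeloid cells, was 9.68-fold lower (8.85 to 10.6), H2-Aa, an MHC class II chain, 7.59-fold (6.13 to 9.49), Vim (vimentin) 10.6-fold (6.94 to 16.9) and Hba-a1, a globin gene with a close copy, 14.8-fold (8.42 to 28.4). Dcn, which encodes decorin, had 186 and 0 reads, 72.3-fold lower against the floor of 3 reads (at least 58.2-fold by the 95% interval). The complement gene C1qa was an exception, 2.04-fold higher (1.82 to 2.30), although C1qb and C1qc in the same list had log2 ratios of -1.05 and -1.04. Cd79a (450 and 511 reads) and Lck (125 and 141 reads) were near equal, although Cd79b was at 0 in the library labelled knockout. C1qa, C1qb, C1qc, Cd79a and Lck were picked out after their values were seen. Endothelial genes, by contrast, had a median of -0.16, inside the random range (percentile 7.40; 0 of 8 past 1.5-fold).

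**Figure D2:**
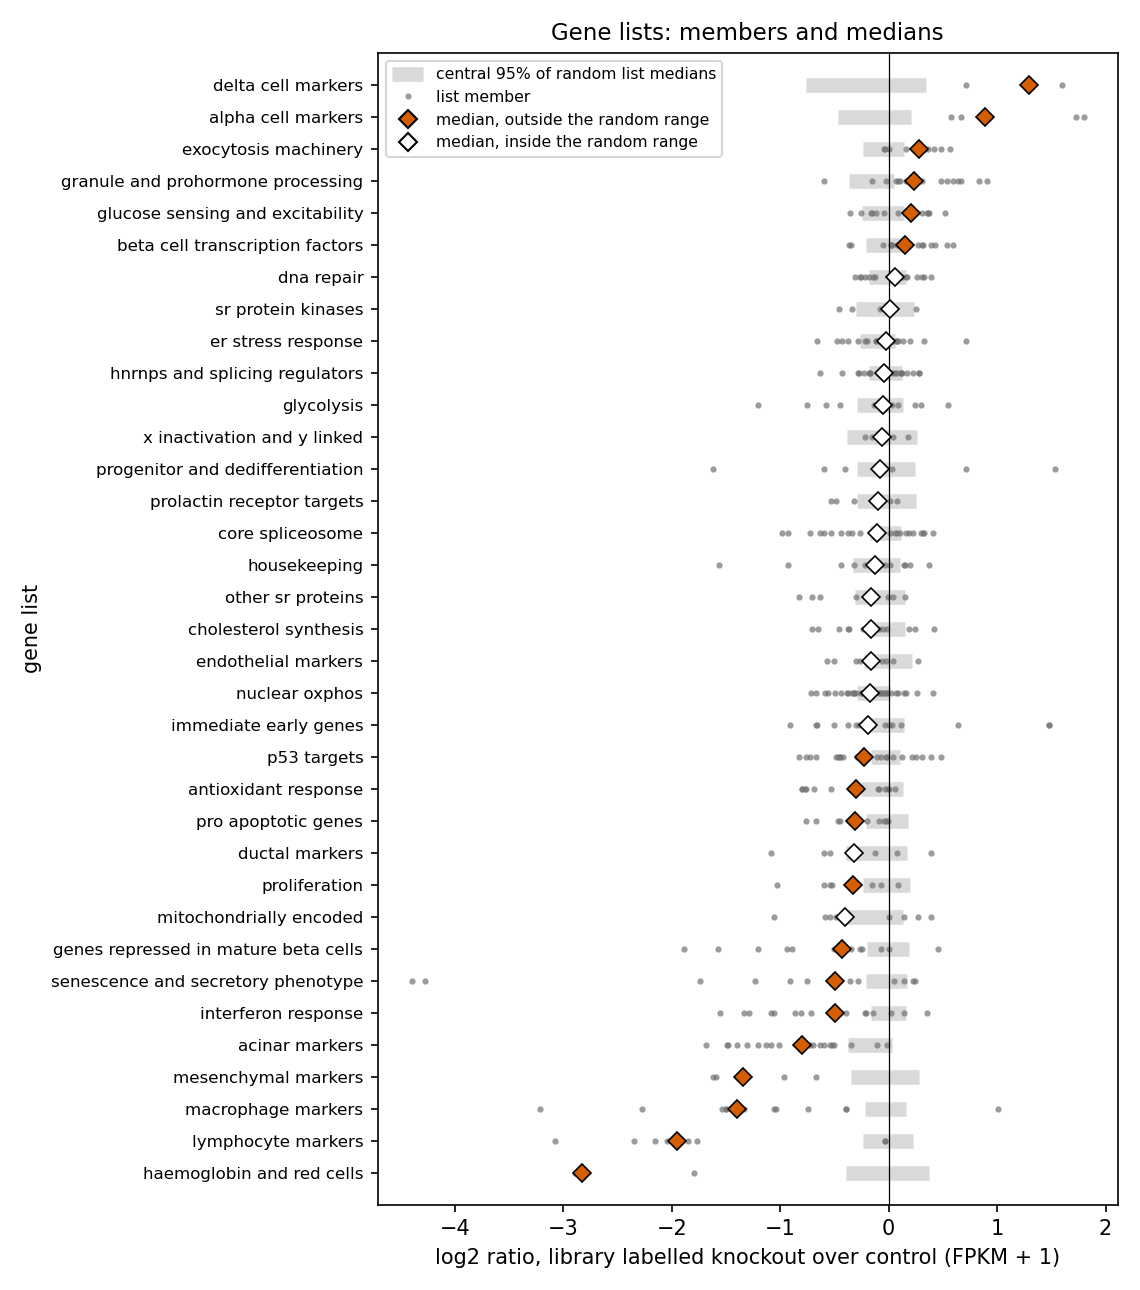
Log2 ratios of FPKM + 1, library labelled knockout over control, for 35 gene lists: small points are members with a mean of at least 1 FPKM, diamonds are list medians (orange where outside the central 95% of 10000 random list medians) and grey bars are that random range. With that filter and a pseudocount of 1 FPKM, the delta and alpha cell medians are 1.30 and 0.89, and the red-cell, lymphocyte, macrophage and mesenchymal medians lie between -2.82 and -1.34; with no filter the mesenchymal median is -0.46.

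Inflammatory and secreted factors were among the genes with the largest differences. The 10 lowest named genes with a mean of at least 5 FPKM were Jchain, Cxcl5, Reg2, Mmp10, Mmp3, Ccr7, Ccl2, Reg3a, Ifi27l2a and Ubd. Jchain, which joins immunoglobulin monomers, had 2726 reads in the control and 2 in the other library, a ratio of 0.00063 (7.6e-05 to 0.00227). Against the floor of 3 reads, the matrix metalloproteinase gene Mmp3 (573 and 0 reads) was 222.8-fold lower. The chemokine Cxcl5 (705 and 0) was 274.1-fold and the chemokine receptor Ccr7, also at 0, 227.8-fold lower against it. The 95% intervals allow smaller folds, down to 180.6, 222.3 and 184.7 in that order. Ccl2, a monocyte chemokine, was 74.6-fold lower (35.9 to 187) and Reg2 22.0-fold lower (20.7 to 23.4). The senescence and secretory list had a median of -0.49 (percentile 0; 6 of 13 at least 1.5-fold lower) and the interferon list one of -0.50 (percentile 0.01; 8 of 18), with Rsad2 5.03-fold lower (3.89 to 6.57) and Ifit3 2.68-fold lower (2.25 to 3.20). These lists were lower in the same library as the macrophage and lymphocyte lists, whose medians were -1.40 and -1.95. The interferon median was -0.78 with a pseudocount of 0.1 FPKM, -0.20 with one of 5 FPKM and -1.07 with a mean of at least 5 FPKM, and the senescence median was -0.27 with a pseudocount of 5 FPKM and -1.06 as a mean over members.

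The 10 highest named genes were Sfrp5, Gcg, Gpx3, Ttr, Fbp1, Rbp4, Etv1, Egr1, Nostrin and Cpa4. Sfrp5, a secreted antagonist of Wnt signalling, was 4.79-fold higher (3.86 to 5.99), Fbp1, the gluconeogenic enzyme fructose-1,6-bisphosphatase, 3.70-fold (3.07 to 4.49) and Gpx3, a secreted glutathione peroxidase, 3.47-fold (3.29 to 3.65). Etv1, an ETS transcription factor, was 3.36-fold higher (3.13 to 3.61). Egr1, an immediate early transcription factor, was 3.29-fold higher (2.86 to 3.78), while the immediate early list as a whole had a median of -0.19 (percentile 4.04), with 3 of 16 members at least 1.5-fold higher and 3 lower.

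Splicing factor lists stayed inside the random range. Other serine/arginine-rich proteins had a median of -0.16 (percentile 23.0; 3 of 11 at least 1.5-fold lower), core spliceosome genes -0.11 (percentile 14.3; 5 of 26), hnRNPs and splicing regulators -0.05 (percentile 39.9; 1 of 22) and the kinases of SR proteins 0.01 (percentile 57.9; 0 of 7). All of these medians except that of the kinases turned slightly positive with totals set equal without the 20 highest genes. Srsf3 was 1.83-fold lower (1.73 to 1.94) and Srsf5 1.64-fold lower (1.59 to 1.70). In the core spliceosome, Snrpd1 and Snrpe, which encode Sm ring proteins, were 2.04-fold (1.85 to 2.25) and 1.94-fold lower (1.75 to 2.14); genes of this kind have processed pseudogenes that can share their reads.

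The ER stress list was inside the random range, and 4 other stress and growth lists were lower. The ER stress list had a median of -0.03 (percentile 82.1), which turned positive with median centring and with equal totals without the 20 highest genes. In it, Herpud1, a component of ER-associated degradation, was 1.64-fold higher (1.61 to 1.68) and Atf3 was 1.69-fold lower (1.42 to 2.02). Medians were lower for p53 targets (-0.22, percentile 0.37; 4 of 27 at least 1.5-fold lower), pro-apoptotic genes (-0.31, percentile 0.41; 2 of 12), proliferation genes (-0.33, percentile 0.44; 2 of 10) and antioxidant genes (-0.31, percentile 0.84; 5 of 14), and 0 members of these 4 lists were at least 1.5-fold higher. The macrophage and lymphocyte lists were lower in the same library (medians -1.40 and -1.95). Fas, the death receptor in 2 of these lists, was 1.85-fold lower (1.41 to 2.45), Rrm2, a subunit of ribonucleotide reductase, 2.75-fold (2.09 to 3.64) and Hmox1, which encodes haem oxygenase 1, 1.75-fold (1.57 to 1.95). Each of these 4 medians came back inside the random range under at least 1 alternative: with a mean over members for the p53, pro-apoptotic and antioxidant lists, with a mean of at least 5 FPKM for the p53 and proliferation lists, and with the gene length trend removed for the antioxidant list (-0.17). With totals set equal without the 20 highest genes the medians were -0.098, -0.18, -0.20 and -0.14 in the order given. The pro-apoptotic median was -0.14 with a pseudocount of 5 FPKM and -0.20 with no filter, and the proliferation median was -0.18 with that pseudocount and -0.50 with equal totals over all genes.

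The remaining lists were inside the random range. Medians were -0.17 for nuclear oxidative phosphorylation genes (percentile 31.1), -0.40 for mitochondrially encoded genes (percentile 3.20), -0.05 for glycolysis (percentile 58.3), -0.16 for cholesterol synthesis (percentile 5.04), 0.06 for DNA repair (percentile 75.6), -0.08 for progenitor and dedifferentiation genes (percentile 31.8), -0.10 for prolactin receptor targets (percentile 23.4), -0.06 for X-inactivation and Y-linked genes (percentile 42.0) and -0.13 for housekeeping genes (percentile 36.7). Except for the mitochondrially encoded list, the sign of each of these medians turned under at least 1 of the 3 scalings. The mitochondrially encoded median was -0.19 (percentile 37.3) with a mean of at least 5 FPKM and -0.22 (percentile 13.0) with a pseudocount of 5 FPKM. All 4 measured members of the X-inactivation and Y-linked list are Y-linked, so its median says nothing of X inactivation. Within the housekeeping list, B2m, the shared light chain of MHC class I, was 2.99-fold lower (2.79 to 3.20) and Ppia, which encodes cyclophilin A, 1.90-fold lower (1.85 to 1.95). Of the 35 lists with at least 3 measured members, 18 lay outside the central 95% of their random lists, 6 higher and 12 lower, where chance alone would put about 1.75; lists of 1 cell type are correlated, so these are not independent.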

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

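The removal of the gene length trend was chosen after seeing the data; the other 11 of the 12 alternatives were planned. Of the 18 lists outside the central 95% of random lists, 12 stayed outside under every alternative run on them, with the same sign, and 184 of 194 values kept both. The 3 scalings multiply values by a constant per library and so shift a list and its random lists nearly alike. Equal totals over all genes also enlarges the values, so that the pseudocount of 1 FPKM weighs less. Summing rows of 1 symbol leaves most lists unchanged. Under these alternatives a list far from the edge of the random range could hardly have crossed it. Lists near the edge could: immediate early and mitochondrially encoded genes moved outside under a scaling. A scaling turned the sign of 12 list medians near 0. Among 119 named genes 3 of 833 values turned sign (Myc and Prlr with equal totals without the 20 highest genes, Socs2 with the length trend removed), 0 of them among the 602 values of genes reported at least 1.5-fold different, and 62 moved by over 1.5-fold. Changing the pseudocount cannot turn a sign, and the scalings shift the libraries against each other too little to turn a 1.5-fold difference. The 0 of 602 was therefore nearly fixed in advance.

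Numbers of genes at least 2-fold higher and lower, 55 and 226 as reported, were 115 and 359 with a pseudocount of 0.1 FPKM, 9 and 95 with one of 5 FPKM, 97 and 381 with equal totals over all genes, 28 and 121 with a mean of at least 5 FPKM, and 261 and 692 at 1.5-fold. Equal totals without the 20 highest genes gave 85 higher. A smaller pseudocount, a scale with larger values and a lower threshold admit more genes by construction.

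Medians that came back inside the random range were those of beta-cell transcription factors at 0.15 (pseudocount 0.1), 0.14 (no filter) and 0.15 (mean of at least 5 FPKM), p53 targets at -0.25 (mean of at least 5 FPKM) and -0.20 (mean over members), proliferation at -0.23 (mean of at least 5 FPKM), glucose sensing at 0.11, pro-apoptotic genes at -0.31 and antioxidant genes at -0.37 (mean over members), and antioxidant genes at -0.17 (length trend removed). Medians that moved outside were those of immediate early genes at -0.27 (pseudocount 0.1), -0.078 (equal totals without the 20 highest genes), -0.23 (equal totals over all genes) and -0.30 (mean of at least 5 FPKM), and mitochondrially encoded genes at -0.40 (equal totals over all genes) and -0.39 (no filter). Other alternatives put both lists further inside. Immediate early genes were at -0.071 (percentile 15.2) with a pseudocount of 5 FPKM. Mitochondrially encoded genes were at -0.19 (percentile 37.3) with a mean of at least 5 FPKM. Means over members were -0.02 for immediate early genes and -0.27 for mitochondrially encoded genes. For these lists the cause was not tested. No paired analysis was possible because each group has 1 library. Depth limits low genes: for a gene at 0 reads in the library labelled knockout, the fixed floor of 3 reads is 0.162 reads per 1000000.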

Other observations

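All tests in this part were chosen after the results they bear on were seen, and all genes it names outside the fixed rule were picked after their values were seen.

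Neurog3, the transcription factor that specifies endocrine progenitors, had 37 reads in the control and 183 in the other library, 4.24-fold higher. Its interval starts at 2.97. Fam241b, which overlaps it on the opposite strand, was 1.21-fold higher. Fev, a transcription factor that follows Neurog3 in endocrine development, was 4.69-fold higher and Gfra3, a receptor of the GDNF family, 6.11-fold higher. The progenitor list, which holds Neurog3, was inside the random range (median -0.08, percentile 31.8), with 2 of 7 members at least 1.5-fold higher and 2 lower. Edn3 (endothelin 3), Pappa2 (a protease of IGF-binding proteins) and the amino acid transporter Slc38a5 were 5.30-fold, 4.46-fold and 2.72-fold higher. Fos was 3.68-fold higher.

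Of 76 ribosomal protein genes with a mean of at least 1 FPKM, 58 were at least 1.5-fold lower and 0 higher, with a median log2 ratio of -0.76, which stayed between -0.77 and -0.59 under the other scalings and was -0.65 with the length trend removed; many of these genes have near-identical pseudogenes, so their counts are uncertain. Across 10079 genes the log2 ratio went with gene length (Spearman's rho 0.248 across genes, which are not replicates): over 8 classes of length the median went from -0.20 in the shortest to 0.09 in the longest. Regenerating-family genes other than those already named were lower too, Reg3b 8.24-fold and Reg3g 8.02-fold. There were 35 genes with at least 60 reads in the control and at most 1 in the other library, and 0 the other way round. Among mitochondrially encoded genes, mt-Co1 had 41588 and 58695 reads but mt-Co2 only 30 and 19.

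Alpha and delta cell genes were higher while acinar genes were lower. Fewer acinar or beta cells alone would raise the share of every other cell type alike. The alpha and endothelial lists did not move alike: the lower quartile of the alpha list lay 0.72 log2 units above the upper quartile of the endothelial list. Other cell types were lower in the same library (medians -1.40 for macrophages and -1.34 for mesenchymal cells), so endothelial genes are no fixed reference. The comparison therefore cannot decide how much of the rise fewer acinar or beta cells explain. Of 10 beta-restricted genes, 6 were higher and 4 lower (median log2 ratio 0.03), from Ins2 at 0.91 to Mafa at -0.37, and 8 were higher with equal totals without the 20 highest genes. Islets from different parts of the pancreas, and an effect of the genotype, stay open and untested.

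Immune, stromal and red-cell genes were lower. The library labelled knockout had more reads but fewer genes with reads (15271 against 17070) and fewer genes with 1 to 9 reads (2289 against 3727), as a library with fewer different molecules, or one with fewer cell types, would have. As the whole cause, a loss of low-count genes of any kind is argued against: at 50 to 500 control reads, 4.05% of other list members (7 of 173, acinar genes left out) were at or below 0.2 of the control, against 53.3% (16 of 30) of the immune, stromal and red-cell members. Fewer white blood cells among the islets are a candidate explanation for the immune part. Of 17 genes of white blood cells outside the fixed lists, 11 passed the filter of at least 1 FPKM. Genes high in the control alone can pass that filter. Of the 11, 9 were at least 1.5-fold lower and 0 higher, with a median log2 ratio of -1.87 (Cd52 247 and 11 reads, Cd53 435 and 32). They were listed after the immune lists were seen to be lower, so they repeat the pattern in more genes and are not independent support. Ptpn6 (380 and 395 reads), Cd79a, Lck and C1qa were not lower. C1qb, C1qc and Cd79b were lower, so members of 1 list did not all move alike. Why fewer white blood cells would be there, by islet preparation or genotype, was not tested, nor was the stromal and red-cell part.

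Srsf1 was not lower in the library labelled knockout. Reads from islet cells that do not express Cre may hide a loss in beta cells. The lower bound of the ratio, 0.873, leaves room for a small loss, but it covers counting error only and holds for the main scaling. The log2 ratio was -0.02 as reported and with equal totals over all genes. It was 0.05 with median centring and 0.13 with equal totals without the 20 highest genes. The share of Srsf1 transcripts that beta cells contribute is unknown, so a hidden loss cannot be told apart from no loss. Reads from parts of the transcript that a recombined allele keeps are also possible, because 14.7% of the exon length is coding, but the deleted exons are not stated and the deposited value does not separate exons. No value here tests whether recombination took place.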
